A study of Danio rerio with 4 samples.

How the data were processed

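Per the labels, RNA was recovered with anti-FLAG beads from zebrafish embryos injected with mRNA for FLAG-tagged Ddx3xb and sequenced, in 4 samples that the labels place at 2 hpf and 4 hpf with 2 biological replicates each. The protocols say that embryos were lysed in a buffer with a mild detergent, lysates were held with anti-FLAG M2 beads, and libraries were made from the recovered RNA with a SMARTer small RNA kit. The molecule is labelled polyA RNA. The genotype is labelled wild type. Sample descriptions also carry the word control, which is not explained further in the sources used here.

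The deposited values are RPKM, made by the authors, in 1 table per age. Each table has an Ensembl gene ID and 1 value per gene, with no header. That the value is a mean over the replicates is taken from how the tables were named, since nothing in them states it, and how the mean was formed is not given in the sources used here. Every listed value is above 0, and a gene in only 1 table was taken as 0 in the other. Per the submitters' processing notes, cutadapt 1.13, Trimmomatic 0.36, Bowtie, TopHat2 2.1.1, MACS2 2.0.10 and bedtools 2.16.2 were used, with genome build Zv9. The notes give neither the order nor the role of these tools, and the annotation, the counting program and the read total in the RPKM denominator are not given in the sources used here. RPKM shares its denominator among all genes, so a table in which a few features take more of the reads shows lower values for the rest. The depth of the libraries is unknown, because the tables give neither counts nor gene lengths, and no counting interval was computed. Reads that fit several near-identical genes may have been divided or dropped by the authors' counting, which affects gene copies and ribosomal RNA entries most.

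Gene symbols came from a reference table of Ensembl IDs, which named 20039 of the 27205 IDs in either table (73.7%). It leaves 7166 without a symbol, and unnamed IDs held 83.8% of the summed RPKM in the table labelled 2 hpf and 66.5% in that labelled 4 hpf. Symbols are printed as that table gives them, some in human style. A symbol can sit on several IDs, which was so for 1247 symbols on 2613 IDs, and each ID was kept as its own gene. No genome or annotation of build Zv9 was used here, so positions and gene lengths are not given.

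The comparison between ages was the difference of log2(RPKM + 1), table labelled 4 hpf minus table labelled 2 hpf, for genes with at least 1 RPKM in either table. A gene was called at an absolute difference of 1 or more. With 1 mean per age no test is possible, so no p-value is given and a call is a difference of size between 2 tables. Before the data were examined, 22 gene lists, the rule for named genes and the alternatives were fixed. For a list with at least 5 measured genes, the median difference was placed among 10000 random lists of the same size drawn from the named tested genes in 10 bins of mean level, and a list outside the central 95% was counted as standing apart. This percentile describes these tables and is not a test over replicates. Lists defined by a symbol pattern take in some genes whose symbols only begin alike. Members of a list were matched by symbol without regard to case.

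Named genes are ddx3xb and ddx3xa, the 15 genes with the largest difference in each direction among those with at least 10 RPKM in either table and a symbol that is not a clone name, the 10 highest entries of each table, and for each list up to 2 members with the highest level and up to 2 with the largest difference among those with at least 5 RPKM. This gave 106 genes, not all of which are printed. The exceptions are named as such. The results of 1 fixed list and of 1 gene family are not reported here, though the counts over all lists include that list.

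The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 RPKM, rescaling to an equal sum, scaling to an equal median ratio of the genes with at least 5 RPKM in both tables, quantile normalization, scaling on the sum without the 100 highest genes, use of only the genes listed in both tables, a 4-fold threshold, and detection at 0.5 or 5 RPKM. Matching list members through older symbols, and the bait scaled on the sum without the 100 highest genes, were added after the data were seen. Without replicate values, a correlation was counted as moved when it differed by over 0.05 and a share when it differed by over 5 percentage points. These tolerances were chosen here and do not come from replicates.

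The calculation was tested on simulated data made from the table labelled 2 hpf alone. The assumed noise SD was 0.3 on the log2 scale at every level, with no overall shift between the ages. Changes were planted only in genes with at least 5 RPKM, so recovery among lower genes is not covered. Of the genes given a log2 change of 1.5, 86 of 100 were called, and of those given 3, 100 of 100. Of 11681 unchanged genes, 2 were called. Of 40 random lists, 3 fell outside the central 95%, and a list lowered by 1 on the log2 scale was found below it. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.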

Results

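The data describe RNA from precipitates aimed at Ddx3xb, a DEAD-box RNA helicase, in early zebrafish embryos. Per the labels, embryos of wild-type genotype were injected with mRNA for FLAG-tagged Ddx3xb, collected at 2 or 4 hours post-fertilization (hpf), and lysed for RNA immunoprecipitation with anti-FLAG beads followed by sequencing (RIP-seq). The labels list 4 samples, 2 biological replicates at each age. The descriptions of all 4 also say control without saying of what, and in precipitates without the tagged protein the values would be background. The values analysed were the authors' mean RPKM (reads per kilobase of gene, scaled to the number of reads) per gene and age, so no replicate spread, SD or n stands behind any value here, no difference was tested against replicate error, and the depth of each library is unknown. No input or mock precipitate is among the samples, so a value is abundance in the precipitate and not enrichment over the embryo's RNA. Each table is named below by the age in its label, because genes of the zygotic genome, which embryos switch on with age, were more abundant in the table labelled 2 hpf. Every direction given here rests on those labels.

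A few features held a large part of the summed RPKM in both tables. RPKM is divided by gene length, so these are not shares of reads or of the precipitated RNA, which are unknown without counts or lengths. In the table labelled 2 hpf, the 2 highest entries held 64.8% of the summed RPKM and the 10 highest held 82.1%. The matching shares in the table labelled 4 hpf were 48.4% and 62.3%. Of the 10 highest entries of each table, 8 had no symbol. The named entries among them were 5_8S_rRNA, a ribosomal RNA gene, at 22254 and 22330 RPKM in the tables labelled 2 and 4 hpf, and si:dkey-153m14.1 at 6231 and 2979 RPKM. The tables labelled 2 and 4 hpf listed 25804 and 24904 genes, of which 11471 and 11556 reached 1 RPKM, with 9686 doing so in both. At a stricter level of 10 RPKM the numbers were 2487 and 4244. Over the 13143 genes listed in both tables with at least 1 RPKM in either, log2(RPKM + 1) values had a Pearson correlation of 0.81 and a Spearman correlation of 0.75. Both are correlations across genes, which are not independent replicates.

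The design compares the 2 ages, which lie before and around the main activation of the zygotic genome. Most genes had a higher RPKM in the table labelled 4 hpf. Of 13341 genes with at least 1 RPKM in either table, 4409 were at least 2-fold higher there and 1452 at least 2-fold lower on the log2(RPKM + 1) scale, a scale that understates the difference of low genes. The median difference over all of them was 0.66, or 1.58-fold. This balance followed the scaling of the tables. Higher genes made up 75.2% of those past the threshold with RPKM as deposited, 84.8% after rescaling to an equal sum, 39.6% after quantile normalization, 27.8% after scaling on the sum without the 100 highest genes and 12% after scaling to an equal median ratio. At a 4-fold threshold the share was 46.0%. Relative to the median difference of 0.66, 1047 genes lay at least 2-fold above and 2832 at least 2-fold below. Gene groups are therefore described relative to that median, and each group's median is placed among 10000 random lists of the same size matched on mean level.

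The transcript of the bait, ddx3xb (ENSDARG00000005774), stood at 97.9 RPKM in the table labelled 2 hpf and 194 RPKM in the table labelled 4 hpf, rank 139 and rank 104 of all genes. Reads from the injected and the embryo's own ddx3xb cannot be separated in these values, and the protocol is given for both ages alike, so the level does not distinguish the labels. Its difference of 0.98 became 1.38 after rescaling to an equal sum, 0.26 after quantile normalization and -0.05 after scaling to an equal median ratio. The paralog ddx3xa (ENSDARG00000020573) was at 19.7 and 73.9 RPKM. Among 28 measured genes matched as DEAD-box helicases by symbol alone, 4 lay at least 2-fold above the median of all genes and 3 at least 2-fold below. The group's median of 0.96 was at percentile 31.2 of the matched lists. DDX21, a nucleolar helicase, had 137 and 325 RPKM in the tables labelled 2 and 4 hpf, and DDX11 had 5.34 and 25.4 RPKM.

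Developmental genes of the zygotic genome were higher in the table labelled 2 hpf. Of 26 measured early zygotic genes, 23 lay at least 2-fold below the median of all genes in the table labelled 4 hpf against that labelled 2 hpf, and none lay 2-fold above. Their median difference was -1.16, at percentile 0 of the matched lists, whose central 95% ran from 0.25 to 0.95. With a pseudocount of 5 the median was -0.61 and without a filter, over 37 genes, -0.76, both at percentile 0. The notochord transcription factor gene noto was at 125 RPKM in the table labelled 2 hpf and 9.21 RPKM in the table labelled 4 hpf. The mesodermal T-box gene tbx16 was at 44.2 and 1.25 RPKM, and the homeobox gene irx7 at 62.1 and 28.0 RPKM.

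Genes of the first tissues to separate from the blastoderm went the same way. Of 10 measured genes of the enveloping layer, the outer epithelium of the embryo, 9 lay at least 2-fold below the median of all genes, with a group median of -2.14 at percentile 0. The size of this median depended on the settings, at -3.28 with a pseudocount of 0.1, -0.97 with a pseudocount of 5 and -0.51 over the 15 genes listed without a filter, all at percentile 0. The keratin genes krt4, krt92 and krt18a.1 had 17.8, 13.9 and 18.1 RPKM in the table labelled 2 hpf and 0.356, 0.0853 and 0.437 RPKM in the table labelled 4 hpf. The transcription factor gene grhl3 was closer, at 27.1 and 17.9 RPKM. The adhesion gene epcam was the exception, at 36.8 and 71.5 RPKM. All 7 measured genes of the yolk syncytial layer, the multinucleate layer over the yolk, lay at least 2-fold below the median of all genes, and the group median of -1.32 was at percentile 0.07 (-2.90 at percentile 0.01 with a pseudocount of 0.1 and -0.57 at percentile 0.02 with a pseudocount of 5). The apolipoprotein gene apoc1 was at 22.3 and 0.957 RPKM and the homeobox gene mxtx1 at 5.77 and 0.244 RPKM.

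**Figure D1:**
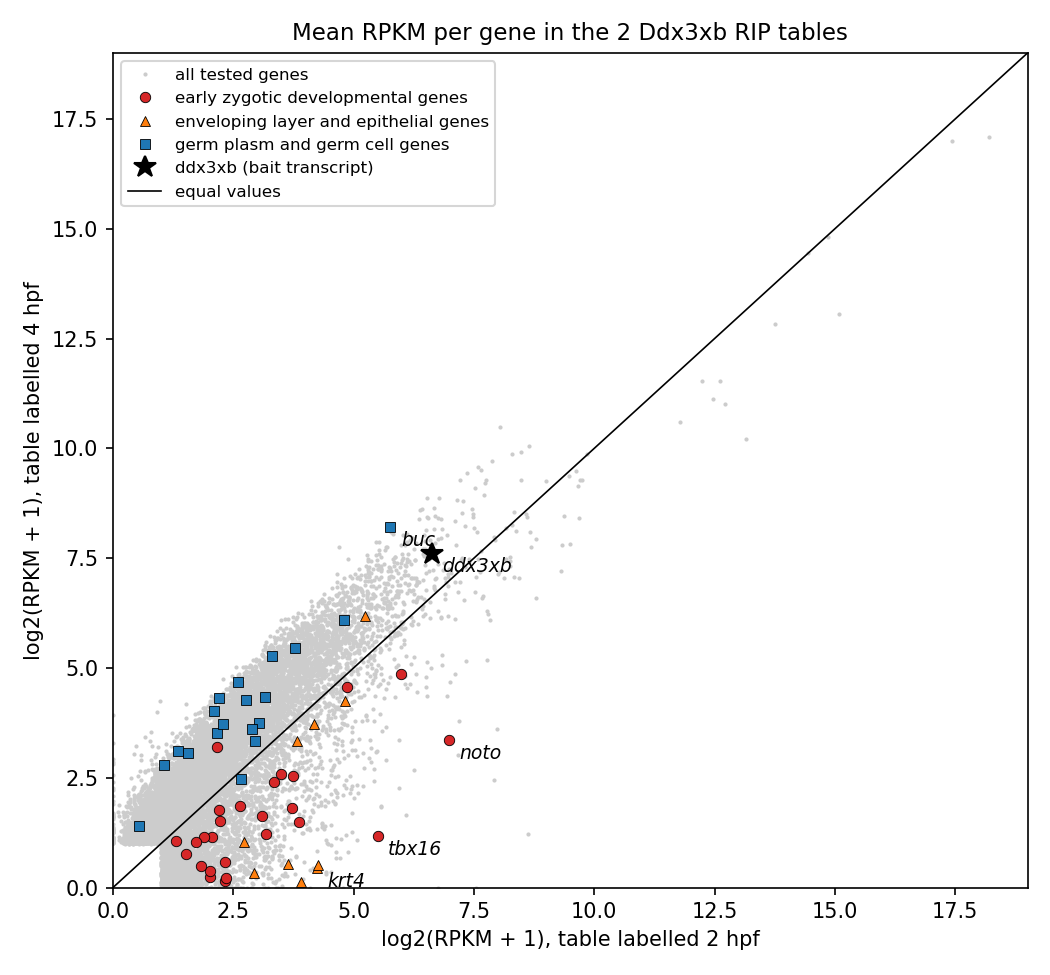
Each point is a gene at its log2(RPKM + 1) in the table labelled 2 hpf (horizontal axis) and in the table labelled 4 hpf (vertical axis), with the 13341 tested genes in grey, 3 gene lists in colour, the bait transcript ddx3xb as a star, and a line where both values are equal. Of the early zygotic genes 25 of 26 lie under the line and of the germ plasm genes 18 of 19 lie over it, in values as deposited.

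Maternal regulators of genome activation and of the embryonic axis lay low as a group. None of the 12 measured lay 2-fold above the median of all genes and 2 lay at least 2-fold below, with a group median of 0.11 at percentile 0.20. YBX1, an RNA-binding protein gene, was at 102 and 129 RPKM in the tables labelled 2 and 4 hpf, and SMAD2, a transducer of Nodal signals, at 18.9 and 53.7 RPKM. The genome activators pou5f3 (62.1 and 59.4 RPKM) and nanog (61.9 and 43.6 RPKM) are named for their role, a choice made after their values were seen.

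Among the fixed lists, germ plasm and germ cell genes were the only one above its random range. Of 19 measured, 8 lay at least 2-fold above the median of all genes and none 2-fold below. The median of 1.5 was at percentile 99.8, and was 0.59 at percentile 99.97 after scaling to an equal median ratio. The gene buc, which encodes the germ plasm organizer Bucky ball, was at 53.4 RPKM in the table labelled 2 hpf and 295 RPKM in the table labelled 4 hpf. TDRD1, a tudor gene of the piRNA pathway, was at 3.64 and 18.9 RPKM, and hook2 at 26.8 and 67.7 RPKM. Of 25 measured oocyte and egg genes, 4 lay at least 2-fold above the median of all genes and none 2-fold below, but the median of 1.14 was within the random range, at percentile 86.1. Examples are cth1, a zinc finger gene, at 39.0 and 135 RPKM and the egg envelope gene zp3b at 2.12 and 10.9 RPKM. The germ plasm and egg lists share 2 measured genes, buc among them.

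Cytosolic ribosomal protein genes lay low. Among 73 measured cytosolic ribosomal protein genes, 31 lay at least 2-fold below the median of all genes and none 2-fold above, and the median of -0.26 was at percentile 0 against a random range of 0.81 to 1.24. The sign of this median turned to 0.12 after rescaling to an equal sum, while its percentile stayed at 0. RPS29 was at 23.9 and 7.71 RPKM in the tables labelled 2 and 4 hpf, and RPS14, one of the most abundant members, at 312 and 303 RPKM. Of 56 measured translation initiation factor genes, a list matched by symbol that also holds kinases and binding proteins of these factors, 13 lay at least 2-fold above and 3 at least 2-fold below, with a median of 0.93 at percentile 35.5. The GTPase gene eif5b was at 108 and 464 RPKM and EIF2S2 at 153 and 447 RPKM. The 7 elongation and release factor genes had a median of 0.67 at percentile 21.1, with eef1a1l1 at 64.1 and 65.2 RPKM. Genes of messenger ribonucleoprotein particles, P-bodies and stress granules were within the random range, with 6 of 36 above, 2 below and a median of 0.98 at percentile 40.3. Of these, FMR1 was at 6.23 and 32.6 RPKM, ATXN2 at 5.54 and 31.3 RPKM, and the poly(A)-binding protein gene pabpc1a at 178 and 361 RPKM, a difference of 1.02 that came to -0.0051 after scaling to an equal median ratio.

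Genes of nuclear RNA processing lay on the side of the zygotic genes. Of 27 measured spliceosome and nuclear RNA-binding genes, 17 lay at least 2-fold below the median of all genes and none 2-fold above, with a median of -0.68 at percentile 0. The splicing factor gene srsf5a was at 39.9 RPKM in the table labelled 2 hpf and 6.28 RPKM in the table labelled 4 hpf, hnrnpa0a at 6.63 and 0.765 RPKM, and khdrbs1a at 287 and 176 RPKM. SF3B2 was nearly level, at 53.3 and 55.4 RPKM. Of 13 histone genes, 3 lay at least 2-fold below, and the median of 0.38 was at percentile 2.33, a place just outside the random range that was lost under 4 of the settings tried. The histone H3.3 gene h3f3a was at 39.5 and 9.25 RPKM, and h2ax at 75.7 and 132 RPKM.

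Mitochondrially encoded transcripts lay low. Of 13 mitochondrially encoded genes, 6 lay at least 2-fold below the median of all genes and none 2-fold above, with a median of -0.08 at percentile 0.04 (0.33 after rescaling to an equal sum). MT-CO2 was at 278 and 130 RPKM in the tables labelled 2 and 4 hpf, and MT-ATP6 at 385 and 364 RPKM. The 75 nuclear-encoded genes of the respiratory chain and ATP synthase, matched by symbol and including assembly factors, had 1 member at least 2-fold above and 11 at least 2-fold below, with a median of 0.58 at percentile 6.78. That list fell below its random range after scaling to an equal median ratio (-0.30, percentile 2.40) and after quantile normalization (-0.081, percentile 0.85), and the difference between both mitochondrial lists was not tested. ATP5F1B was at 23.9 and 99.7 RPKM and cox6b2 at 19 and 4.32 RPKM. The 36 genes matched as proteasome subunits, among them a gene whose symbol only begins like a subunit's, had a median of 0.90 at percentile 26.8, with PSMD1 at 15.1 and 56.5 RPKM.

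Cell cycle genes lay within the random range. Of 27 cyclins and mitotic regulators, 3 lay at least 2-fold above the median of all genes and 2 at least 2-fold below, with a median of 0.77 at percentile 4.86, or -0.15 at percentile 2.14 after quantile normalization. The kinase gene plk1 was at 56.3 and 170 RPKM in the tables labelled 2 and 4 hpf, and GMNN, the gene of the replication licensing inhibitor geminin, at 117 and 166 RPKM. Of 14 heat shock and stress genes, 2 lay at least 2-fold above and 5 at least 2-fold below. Their median of -0.05 was at percentile 0.29, but it was 1.18 at percentile 55.7 when only genes with at least 5 RPKM were kept. The small heat shock protein gene HSPB1 was at 144 and 7.11 RPKM, while the chaperone gene HSP90AB1 was at 354 and 966 RPKM.

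Markers of cells that embryos of these ages should lack were near the floor. Of 24 listed genes of differentiated tissues such as blood, muscle and liver, 1 reached 1 RPKM, the transferrin gene tfa at 2.1 RPKM in the table labelled 2 hpf and 0.258 RPKM in the table labelled 4 hpf, named because it was the only one. The 6 interferon and innate immune genes had a median of -0.23 at percentile 9.64, with isg15 at 7.63 and 3.08 RPKM. The 12 common reference genes had a median of 0.51 at percentile 8.90, and 10 of them had a positive difference, with actb1 at 112 and 333 RPKM and actb2 at 36.5 and 137 RPKM. The others, RPL13A (6.98 and 6.80 RPKM) and b2m (1.12 and 0.765 RPKM), are named because they were the only negative ones.

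**Figure D2:**
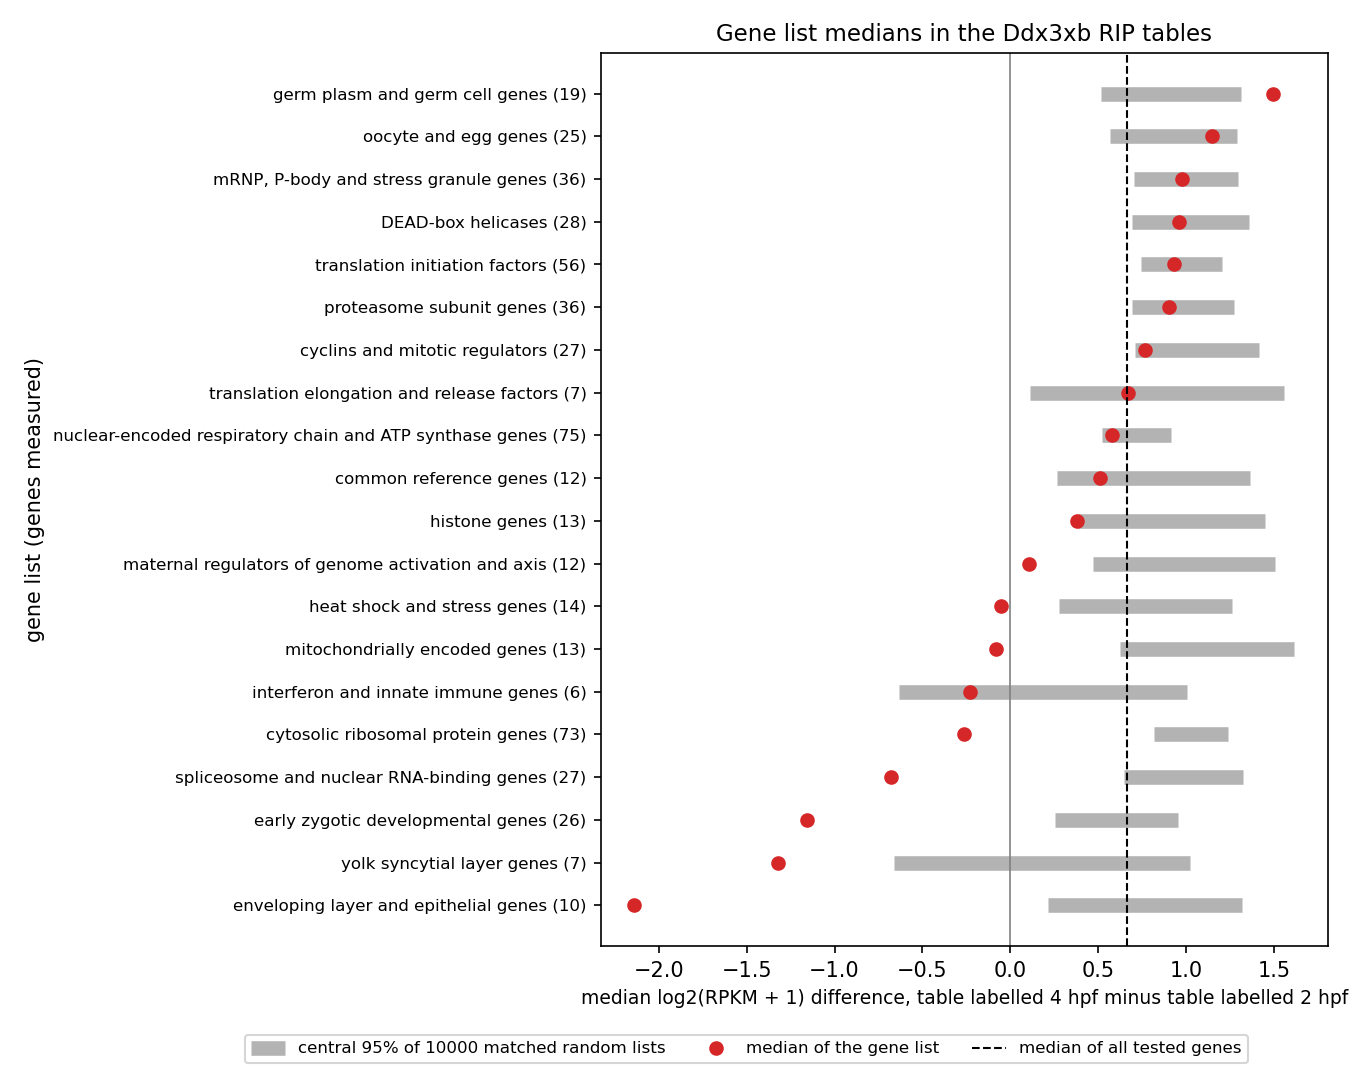
Median log2(RPKM + 1) difference, table labelled 4 hpf minus table labelled 2 hpf, of 20 fixed gene lists with at least 5 measured genes (red points), the central 95% of 10000 level-matched random lists (grey bars) and the median of all tested genes (dashed line at 0.66). Of these lists, 9 lie below their grey bar and 1, the germ plasm list, above it; the sign of the median changes under at least 1 of 3 scalings for 12 lists, which are those with medians between -0.26 and 0.98 apart from the translation initiation and interferon lists.

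Among single genes with at least 10 RPKM in either table, the widest differences were toward the table labelled 2 hpf. The gene stm, known for starmaker of the ear stone, was at 394 RPKM there and 1.34 RPKM in the table labelled 4 hpf, a difference of -7.40. The next were tbx16 (-4.33), the amino acid transporter gene SLC7A8 at 22.1 and 0.273 RPKM, HSPB1 (-4.16) and the envoplakin gene evpla at 20.7 and 0.230 RPKM. The chromatin gene hmgn6 was at 28.5 and 0.749 RPKM and the microRNA gene MIRLET7F1 at 32.5 and 1.12 RPKM. In the other direction the differences were smaller. MLLT1, a gene of transcription elongation, led with 24.8 RPKM in the table labelled 2 hpf and 216 RPKM in the table labelled 4 hpf, a difference of 3.07. REV3L, the catalytic subunit gene of DNA polymerase zeta, followed at 10.2 and 67.5 RPKM, and rasef2 at 28.7 and 178 RPKM. Others among the 15 highest were the histone chaperone gene NASP at 263 and 1422 RPKM, the methyltransferase gene DNMT1 at 43.4 and 232 RPKM, brca2 at 9.57 and 56.1 RPKM and the synaptonemal complex gene SYCP1 at 10.1 and 59.5 RPKM. Entries with clone names or no symbol were passed over, 15 at the lower and 10 at the higher end of this ranking. Values of near-identical gene copies are uncertain, since reads they share may have been divided between them.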

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

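Matching list members through older symbols, and the bait without the 100 highest genes, were the only settings chosen after the data were seen. No paired analysis was possible because each age has a single mean column with no replicate values, and leaving out a replicate was not run for the same reason. Limits are the unknown depth, the absent replicate spread and the lack of an input or mock among the samples. Against 4409 higher and 1452 lower genes, there were 1907 and 371 with a pseudocount of 5, 347 and 2533 after scaling to an equal median ratio, 849 and 2205 after scaling without the 100 highest genes, and 291 and 342 at a 4-fold threshold. Rescaling to an equal sum gave 6668 higher genes, quantile normalization 1369, and a filter of 5 RPKM 607 lower genes. Genes at 5 RPKM or more numbered 4703 and 6402 in the tables labelled 2 and 4 hpf. The Pearson correlation across genes was 0.75 with a pseudocount of 0.1, 0.89 without a filter and 0.71 with a filter of 5 RPKM, and the Spearman correlation 0.86 and 0.66 under those filters. Shares held by the highest genes moved by less than 5 points without mitochondrially encoded and named ribosomal RNA genes. Entries without a symbol, 8 of the 10 highest in each table, were kept in this setting. It therefore does not tell how much of the shares is ribosomal RNA. The bait passed the threshold, at 1.38, only after rescaling to an equal sum.

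Of 166 list medians under an alternative, 157 kept their place inside or outside the random range. The verdict on lists was first based on the sign of the median and was changed to its percentile after that output was seen, because scaling shifts all medians together. The early zygotic median stayed between -1.78 and -0.61 over 8 alternatives. The histone median fell inside the range with a pseudocount of 5 (0.27), without a filter (0.32), after rescaling to an equal sum (0.78) and after quantile normalization (-0.38). The heat shock median was 1.18 with a filter of 5 RPKM, which leaves fewer of its genes, and -0.34 after quantile normalization. The respiratory median left the range after scaling to an equal median ratio (-0.30) and quantile normalization (-0.081), and the cyclin median after the latter (-0.15). By sign alone, 12 of 21 medians changed under a scaling, such as the maternal regulators (-0.84 at an equal median ratio), the ribosomal protein genes (0.12) and the mitochondrially encoded genes (0.33), both at an equal sum. The yolk syncytial and interferon lists have no value with a filter of 5 RPKM, and the late tissue list has too few measured genes for a median. Of 530 values of named genes, 449 kept their side of the threshold, 56 lost it and 21 gained it. Of the others, pabpc1a turned to -0.0051 at an equal median ratio and, after quantile normalization, ENSDARG00000082123 to 0.13 and si:dkey-153m14.1 to 0.51. ENSDARG00000070212 came to 0, which quantile normalization forces on an entry at rank 1 in both tables. Signs were compared only for genes past the threshold in RPKM as deposited. A gene short of it that changed sign was counted as kept or gained, and ddx3xb at an equal median ratio counts as kept. These counts therefore do not describe how stable the directions were. Beyond the smaller set of genes under a filter, the cause was not tested.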

Other observations

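The tests of scaling, of paralog pairs and of the few dominant features, and the families described next, were chosen after the values they use had been seen. The families come from a look through 60 symbol prefixes, of which 55 had at least 8 tested genes, and 12 were followed up. As they were picked with their values in view, their percentile among random lists would only restate the choice and is not given. Their members named here lie outside the rule for named genes and were chosen after their values were seen, as were mych, MCM6 and ADD3 below. Genes of microRNAs lay on the side of the table labelled 2 hpf. Of 35 measured, 26 lay at least 2-fold below the median of all genes and none 2-fold above, with a median of -1.21, and 21 of them were not listed at all in the table labelled 4 hpf against 4 in the other. These genes sit near the floor, with 33 of the 35 below 5 RPKM in both tables. Genes this short collect few reads at such levels, so their absence from a table carries little weight. The finTRIM genes, a fish family of TRIM ubiquitin ligase genes, had 9 of 13 at least 2-fold below and a median of -1.17, but 11 of the 13 were below 5 RPKM in both tables. The exceptions were ftr82 at 15.3 and 1.53 RPKM and ftr83 at 12.5 and 1.73 RPKM in the tables labelled 2 and 4 hpf. Keratin genes (median -1.58) lay there too. Claudin genes had a median of -0.78 and 7 of 11 at least 2-fold below. The most abundant claudin genes, cldnd (42.5 and 82.2 RPKM) and cldng (27.6 and 71.0 RPKM), lay above the median of all genes. Both families overlap the enveloping layer list, and cldnd is also in the egg list.

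Myosin and vesicle sorting genes stood on the other side. The 16 myosin genes had a median of 1.49 and 3 members at least 2-fold above the median of all genes, with MYO18A at 11.6 and 50.6 RPKM in the tables labelled 2 and 4 hpf. The 29 vesicle sorting genes of the vps family had a median of 1.28, with 8 at least 2-fold above and 1 at least 2-fold below, and VPS26A at 10.3 and 40.2 RPKM. Tudor domain genes (1.76) and egg envelope genes of the zp family (1.1, with 9 of 14 below 5 RPKM in both tables) overlap the germ plasm and egg lists. Kinesins (1.02), solute carriers (0.57) and znf zinc finger genes (0.57) lay closer to the median of all genes, 0.66.

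Early zygotic genes lie lower in the table labelled 4 hpf, with a list median of -1.16 where the ages would lead one to look for higher values. The highest median of the list over the scalings was -0.79, still below its random lists. The largest rise that any of them gave the table labelled 4 hpf was too small to bring -1.16 to 0. That the median stayed negative therefore decides nothing. A factor common to all genes moves the list and its random lists nearly together. Such a factor alone would not place the list below them. For gastrula or older embryos among those collected as 2 hpf, 0% of 18 listed gastrula and segmentation genes reached 1 RPKM in that table. This gives no sign of such embryos but cannot exclude them. The share was 0% in the table labelled 4 hpf too, and the level that a few older embryos would bring is unknown. Embryos older than 2 hpf but short of gastrulation are not covered by this list. Exchanged age labels, on the tables or on the libraries behind them, remain a candidate explanation: in a second zygotic list chosen before its values were seen, 90.9% of 11 measured genes (10 of them) lay at least 2-fold below the median of all genes, among them mych at 31.1 and 3.13 RPKM in the tables labelled 2 and 4 hpf. The lists of egg-provided transcripts differ in whether, and how clearly, they go the way an exchange would lead one to look for. Germ plasm genes were high in the table labelled 4 hpf (percentile 99.8). All 25 oocyte and egg genes had a positive difference and 17 lay above the median of all genes, though the list was within the random range (86.1). Maternal regulators went the other way. Of these 12 genes, 2 lay above the median of all genes, and the list was at percentile 0.20 of its matched lists. By sign alone, 7 had a positive and 5 a negative difference, with a median of 0.11. The test on the second list repeats the pattern on other genes. It would come out alike if Ddx3xb bound zygotic transcripts differently at each age. Binding acts only on transcripts that are present, and 2 hpf lies before the main activation of the zygotic genome. The 26 measured early zygotic genes had a median of 4.04 RPKM in the table labelled 2 hpf and 1.56 RPKM in the other. At the ages as labelled, binding alone would need these transcripts to be in the embryo before that activation. Whether they were, and whether binding differed, stays open and untested because no input library was used here.

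The median gene lay higher in the table labelled 4 hpf by 0.66. That a few features hold more of the summed RPKM in the table labelled 2 hpf, 86.8% against 69.1% for the 100 highest, is left open as its cause. Scaling on the sum without 1 set of 100 genes, the highest by RPKM added over both tables, brought the median difference to 0.060. This scaling equalizes the remaining genes whatever the cause and so decides nothing. Whether those features are ribosomal RNA could not be read from the tables, as 50 and 40 of the 100 highest entries had no symbol. A difference in how much messenger RNA came down at each age stays open as well.

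Some symbols sit on a pair of genes that went apart, such as MCM6, with 1 copy at 8.83 and 32.6 RPKM and the other at 3.76 and 0.539 RPKM in the tables labelled 2 and 4 hpf, and ADD3, at 10.6 and 40.9 RPKM and at 8.08 and 0.597 RPKM. A division of paralogs into an egg-provided and an embryo-made copy might give such pairs, but they were no more frequent than among random pairs. In 9 of 399 pairs (2.26%) the copies lay at least 2-fold on opposite sides of the median of all genes, against 1.0% to 4.01% in random pairs matched on level. Random pairs can also join an egg-provided and an embryo-made gene. The comparison therefore shows no excess but cannot exclude such a division. The single pairs remain open, since reads shared between copies could move their values too.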
